A study of Mus musculus with 24 samples.

How the data were processed

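RNA-seq was carried out on cultured mouse leukemia cells, in 24 libraries that fall into 8 groups of 3. Per the labels, the cells came from bone marrow of the C57BL/6 strain and grew in medium with the cytokines SCF, IL3 and IL6. In 3 models an inducible leukemia fusion gene (CALM-AF10, MLL-AF10 or MLL-AF9) was switched on or off with doxycycline (DOX), and the vehicle was DMSO. In the 4th experiment, CALM-AF10 cells with a floxed Jak1 gene were compared with cells in which Cre-ER, activated by 4-hydroxytamoxifen, had deleted Jak1. Libraries were made with the Illumina TruSeq kit, per the labels' protocols. The labels give polyA RNA as the input for 3 experiments and total RNA for MLL-AF9. Doses, times and the deleted Jak1 exons are not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Cells without a fusion treated with DOX, and cells given tamoxifen without deletion, were not analysed here.

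The authors deposited 4 tables of values, 1 per experiment, and a table of gene lists. The submitters' processing notes name Bowtie 0.12.2 and the mm9 build, without saying for which step. The counting tool and the gene annotation are not given in the sources used here. The authors deposited whole-number read counts per gene for CALM-AF10, with 24421 genes. Their table for Jak1 has the same number of genes and is called FPKM in its name, but it also holds whole-number counts. Relative to the MLL-AF9 FPKM, its values rose with gene length, with a slope of 0.665 on the log2 scale over 9410 genes, against 0.847 for the CALM-AF10 counts and 9500 genes. The planned limma test of FPKM was therefore replaced by the count test for Jak1. For MLL-AF10 the authors deposited normalized values on a log2 scale, for 24557 entries. These ranged from −1.968 to 14.91, which excludes plain normalized counts. The transformation is not given in the sources used here. Low genes lie close together, as a regularized logarithm would place them, so fold changes in this table are probably shrunken towards 0. For MLL-AF9 the authors deposited FPKM values, with 0.01 as the lowest value, for 24340 genes. Loci in that table lay within 5000 bases of the GRCm38 gene positions for 85.5% of 23137 matched symbols, and of the mm9 positions for 4.99% of 20754. A spreadsheet had turned 27, 26 and 27 gene symbols into dates in the CALM-AF10, MLL-AF10 and MLL-AF9 tables. These genes were tested but not named, as were 5 repeated symbols in the MLL-AF10 table.

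Libraries were assigned to groups from their titles. The CALM-AF10 columns are named on and off, whereas the titles give DMSO and DOX, and no source used here ties the 2 pairs of names. That comparison is therefore off against on, as the column names give it. In the other inducible models it is DOX against DMSO, and in the Jak1 experiment null against floxed. The Jak1 columns are named DMSO and Jak1_Del, and were taken as floxed and null because DMSO is the vehicle of the deletion and the null libraries have the genotype Jak1 deleted. The tables were normalized separately, so each was tested on its own 6 libraries.

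Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) after filterByExpr and TMM scaling. The log2 values of MLL-AF10 were tested with limma 3.58.1 (eBayes with trend) for genes with a mean of at least 3.32, the log2 of 10. The FPKM values of MLL-AF9 were tested with the same limma settings on log2(FPKM + 1), for genes with a mean of at least 1 FPKM. Folds on that scale understate the change of low genes. P-values were adjusted by the Benjamini-Hochberg method, and genes under an adjusted p of 0.05 were called. Levels are printed as TMM-scaled counts, deposited log2 values or FPKM, as mean ± SD over 3 libraries.

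Before the data were examined, the groups, tests, most alternatives, the rule for naming genes and 29 gene lists were fixed. The lists cover the Hoxa and Meis1 program, stem and progenitor genes, interferon and inflammatory programs, Jak-Stat components and targets, granulocyte and monocyte genes, growth and metabolism programs, markers of other cell types, sex-linked genes, fusion loci and housekeeping genes. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison. The count of called members is given over all genes tested and adjusted over the list alone. Named in each comparison were the fusion and target loci, Hoxa9, Hoxa10, Meis1 and the Jak and Stat genes. Added to these were the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, with a higher group mean of at least 10 FPKM or 200 normalized counts. Up to 4 members with the smallest adjusted p were added for each described list. Some genes that the rule names are not reported here. Predicted genes, genes without a symbol and ribosomal pseudogenes were not named. Genes named for shared calls, and the genes in the figures, were chosen after their values were seen. Genes of the stefin A and lysozyme families share sequence with close copies, so the authors' counting could split their reads. No source used here says that reads were counted by strand.

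Shared calls of 2 experiments were set against n1 × n2 / N over the genes tested in both, with a one-sided Fisher's exact test, and no libraries were shared between experiments. The difference between the CALM-AF10 and MLL-AF9 responses of a gene was divided by the root of its summed squared standard errors and referred to a t distribution with summed degrees of freedom, adjusted over the named genes. On simulated data 8% of 10020 unchanged genes had an unadjusted p under 0.05 in that test, so it is somewhat liberal. The MLL-AF10 fold changes were left out of it because of their scale.

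The tests were checked on simulated data with 50 genes at each of 4 fold sizes per comparison. The changed genes were drawn from well expressed genes only, so recovery of low genes was not checked. Genes were simulated independently of each other, without effects shared by the genes of a library. In the CALM-AF10 setting, with 12290 genes, 70% of genes changed 1.25-fold, 96% at 1.5-fold and 100% at 2-fold were recovered, and 21 of 204 calls were false. With the MLL-AF10 spread, 94% and 100% were recovered at 1.25-fold and 1.5-fold among 10551 genes, and 12 of 209 calls were false. With the MLL-AF9 spread, 0%, 42%, 82% and 98% were recovered at 1.25-fold, 1.5-fold, 2-fold and 4-fold among 10782 genes, and 4 of 115 calls were false. In the Jak1 setting 82% and 100% were recovered at 1.25-fold and 1.5-fold among 11533 genes, and 10 of 201 calls were false.

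Same-numbered libraries were checked for pairing through the correlation of their deviations from the group means across genes. In MLL-AF10 these were 0.40, 0.20 and 0.19, all above the bound of 0.1 set for pairing, against at most −0.27, 0.18 and 0.18 with libraries of other numbers. Only the libraries numbered 1 thus stand apart, so the pairing is weak and rests on the data and not on the labels. A fit with the replicate number as a block is therefore given beside an MLL-AF10 result where it changes the call. In CALM-AF10 the correlations were 0.31, 0.16 and 0.018, against at most −0.059, 0.18 and 0.18 with libraries of other numbers. There, too, only the libraries numbered 1 stood apart, and the bound was not met by all. No 2 libraries of a group agreed within sampling noise in the count tables, where the chi-square per degree of freedom lay between 1.68 and 11.5. The biological coefficient of variation was 5.8% for CALM-AF10 and 3.12% for Jak1.

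Alternatives were the replicate block, leaving out each library in turn, no filter and a stricter filter (50 normalized counts or 5 FPKM), a fold threshold, a pseudocount of 0.1, rescaling by median ratios, limma without trend and robust, DESeq2 1.42.0, and RLE scaling in edgeR. Gene lists were also tested with an estimated correlation and with fry. Plots were drawn with matplotlib 3.10.9. Gene positions come from the GENCODE annotation of mm9.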

Results

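The series asked which genes depend on the leukemia fusions CALM-AF10, MLL-AF10 and MLL-AF9, and which genes JAK1 regulates in CALM-AF10 leukemia cells. Each fusion joins a gene involved in leukemia to a partner that recruits chromatin factors, and each model carried it in an inducible form. The 24 libraries formed 4 comparisons of 3 against 3. In the CALM-AF10 table the libraries with the fusion on held 27294924, 24448224 and 40187404 counts and those with it off 37445525, 30922123 and 12130633. The Jak1 floxed libraries held 11743388, 13764632 and 11863191 counts and the null libraries 12264344, 12692055 and 12855096. The depth of the MLL-AF10 and MLL-AF9 libraries is unknown, because their tables hold log2 values and FPKM. In MLL-AF9 the small RNA entry Mir6236 alone made up 74% to 92.4% of the summed FPKM of a library. Values are mean ± SD with n = 3 libraries in each group.

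The loci followed here lie, in mm9, on chromosome 7 from 97278723 to 97357610 (Picalm, which encodes CALM), chromosome 2 from 17976898 to 18134017 (Mllt10, which encodes AF10), chromosome 9 from 44611438 to 44689379 (Kmt2a, which encodes MLL) and chromosome 4 from 87415829 to 87679268 (Mllt3, which encodes AF9). Jak1 lies on chromosome 4 from 100824972 to 100937887. Hoxa9 and Hoxa10 are neighbours on chromosome 6, from 52173099 to 52181088 and from 52181196 to 52190853. Meis1 lies on chromosome 11 from 18780433 to 18918961. The spans are those of whole genes, exons and introns included.

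With CALM-AF10 off, the homeobox genes Hoxa10 and Hoxa9 and their cofactor Meis1 fell, and genes of neutrophil granules rose. Hoxa10 went from 1422 ± 32.1 to 606.9 ± 10.5 normalized counts (log2 fold change −1.23, adjusted p = 3.74e-06 by edgeR's quasi-likelihood test). Hoxa9 went from 3421 ± 69.8 to 1824 ± 65 (−0.91, adjusted p = 8.99e-06) and Meis1 from 2187 ± 110 to 1448 ± 112 (−0.59, adjusted p = 0.00159). Ngp, a neutrophil granule protein, rose from 517.9 ± 91.6 to 1681 ± 69 normalized counts (1.70, adjusted p = 2.72e-05), and S100a9, a subunit of calprotectin, rose from 1979 ± 222 to 6178 ± 1770 (1.63, adjusted p = 0.00197). Of 12366 genes tested, 648 were called, 263 higher and 385 lower with the fusion off, and 76 of them changed at least 2-fold, 17 up and 59 down.

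The loci that form the fusion bear on the column names. Picalm went from 68950 ± 2280 to 40030 ± 3650 normalized counts (−0.78, adjusted p = 0.000275) and Mllt10 from 13020 ± 350 to 9338 ± 616 (−0.48, adjusted p = 0.0018), so transcripts of both fusion partners were lower in the libraries named off. Kmt2a (0.05), Mllt3 (0.08), the histone methyltransferase gene Dot1l (−0.06) and Jak1 (−0.06) were not called, with adjusted p between 0.462 and 0.84. Of the kinases, Jak2 rose by 0.24 and Jak3 fell by 0.30, while Tyk2 at 0.15 missed the threshold (adjusted p = 0.0536) and passed it without off 3 (adjusted p = 0.0265). Stat2, Stat3, Stat4, Stat5a, Stat5b and Stat6 were not called in this comparison, with log2 fold changes from −0.22 for Stat4 to 0.04 for Stat5b.

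The largest falls among well expressed genes were those of Hpgd, which encodes a prostaglandin-degrading dehydrogenase (1029 ± 21.7 to 264.4 ± 33.4, −1.95), the macrophage elastase gene Mmp12 (−1.59), the N-cadherin gene Cdh2 (216.3 ± 9.34 to 71.2 ± 7.72, −1.59), Ipcef1 (−1.48), the transcription factor gene Mecom (1385 ± 16 to 520 ± 64.1, −1.39), Cnksr3 (−1.36), the nucleoside transporter gene Slc29a3 (5560 ± 66.1 to 2170 ± 278, −1.35) and Scml4 (−1.26). The largest rises after Ngp and S100a9 were those of S100a8, the other calprotectin subunit (1.48), Stfa1 (1.26), Fam101b (0.94), the endothelial lipase gene Lipg (0.90), Akr1c18 (0.88) and the neutrophil surface antigen gene Cd177 (0.77).

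Of 22 measured members of the Hoxa and Meis1 program 12 fell and 0 rose, and 14 fell when adjusted over the list alone. Beside Hoxa9, Hoxa10, Meis1 and Mecom, Eya1 fell by 1.02. Camera called the list (adjusted p = 1.59e-36, and 0.00781 with an estimated correlation). Of 22 stem and progenitor genes 8 fell and 2 rose, and 15 fell and 2 rose when adjusted over the list alone. Among the fallen were the costimulatory receptor gene Cd27 (−0.75) and Angpt1 (−0.64). Camera gave adjusted p = 5.29e-10 for this list, and adjusted p = 0.135 with an estimated correlation.

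Granule genes rose in both classes. In the secondary granule and neutrophil list 13 of 29 members rose and 1 fell, against 19 and 1 adjusted over the list alone (camera adjusted p = 6.94e-21, and adjusted p = 0.0879 with an estimated correlation). In the primary granule list 6 of 11 rose and 0 fell, against 7 adjusted over the list alone (camera adjusted p = 6.14e-09, and 0.0423 with an estimated correlation). The serine protease genes Elane (22140 ± 272 to 29990 ± 1220, 0.44) and Prtn3 (0.40) and the myeloperoxidase gene Mpo (0.33) were among them. Of 29 genes of the ATF4 amino acid and stress response 16 rose and 2 fell, against 23 and 4 adjusted over the list alone. The asparagine synthetase gene Asns rose from 3369 ± 140 to 4884 ± 264 (0.54), and Mthfd2 (0.43), Pck2 (0.52) and Cth (1.75) rose as well. Camera gave adjusted p = 2.42e-15 for that list, and adjusted p = 0.105 with an estimated correlation.

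Some interferon and inflammatory genes fell with the fusion off. Of 43 type I interferon response genes 7 fell and 0 rose, against 22 and 0 adjusted over the list alone, among them Parp9 (−0.41), Ifit1 (−1.53) and Samd9l (−0.58). Camera called the list (adjusted p = 4.69e-10, but adjusted p = 0.522 with an estimated correlation). Without the library on 1 the number of fallen members was 20, and without on 2, on 3, off 1 or off 2 it was 0, 1, 1 or 3. With the replicate block it was 28. Of 34 NF-kB and inflammatory genes 6 fell and 0 rose, against 10 and 0 adjusted over the list alone. They include the chemokine genes Ccl3 (2298 ± 112 to 1250 ± 169, −0.86) and Ccl4 (−1.13) and the inducible cyclooxygenase gene Ptgs2 (−1.33). Camera gave adjusted p = 6.2e-05, and adjusted p = 0.522 with an estimated correlation. Of 26 Stat targets 2 rose and 2 fell, against 5 and 5 adjusted over the list alone, and camera did not call the list (adjusted p = 0.852, median 0.024 and mean −0.076). The feedback inhibitor gene Socs3 rose by 0.39, while the kinase gene Pim2 (−0.82) and the receptor gene Il2ra (−0.81) fell.

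The count of CALM-AF10 calls depended on single libraries: it was 343 without on 1, 146 without on 2, 163 without on 3 and 253 without off 2. The calls of S100a8, Stfa1, Akr1c18, Cd177, Mmp12, Parp9, Ifit1, Samd9l, Mpo, Socs3, Cth, Jak2 and Jak3 were each lost without some library, with on 2 or on 3 among those for every one of them and adjusted p at most 0.126, and their log2 fold changes kept their sign.

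With MLL-AF10 exposed to DOX, Hoxa9, Meis1, Hoxa10 and stem cell genes such as Cd34 fell, and calprotectin, granule and monocyte genes rose. Hoxa9 went from 9.512 ± 0.0274 to 8.804 ± 0.0226 deposited log2 units (−0.71, adjusted p = 2.85e-09 by limma), Meis1 from 8.006 ± 0.0278 to 7.418 ± 0.0395 (−0.59, adjusted p = 4.63e-08) and Hoxa10 from 7.157 ± 0.0198 to 6.732 ± 0.0404 (−0.42, adjusted p = 1.03e-06). S100a8 rose from 9.169 ± 0.243 to 10.63 ± 0.379 (1.46) and S100a9 from 9.275 ± 0.159 to 10.73 ± 0.347 (1.45). Of 10553 genes tested 2089 were called, 1121 higher and 968 lower with DOX, but only 5 of these changed by at least 1 log2 unit, 2 up and 3 down. The scale of this table probably shrinks fold changes, so their sizes were not tested against those of the other models. Correlations across genes, list medians and the shared fold threshold below use them as deposited.

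Kmt2a fell by 0.59 (11.74 ± 0.116 to 11.15 ± 0.0648, adjusted p = 1.13e-06) and Mllt10 by 0.34 (10.34 ± 0.0697 to 10 ± 0.0237, adjusted p = 1.65e-05), so transcripts of both partners of this fusion were lower with DOX. Picalm, at 0.09, was not called (adjusted p = 0.0925), but was with the replicate number as a block (adjusted p = 0.0124) and without DOX 1 (adjusted p = 0.0311). Jak2 rose by 0.36 and Jak3 fell by 0.32. Mllt3 (0.11), Dot1l (−0.10), Jak1 (0.12) and Tyk2 (0.14) passed the threshold with adjusted p between 0.0135 and 0.0449. Each of these last 4 calls was lost without DMSO 2, without DOX 2 and without DOX 3, with adjusted p from 0.0559 to 0.127. Stat2, Stat3, Stat4, Stat5a, Stat5b and Stat6 were not called. The nearest was Stat6, at 0.10, with an adjusted p of 0.0547, of 0.00577 with the block and of 0.0331 without DMSO 3.

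The largest falls were those of the ephrin receptor gene Epha7 (8.695 ± 0.09 to 7.373 ± 0.0347, −1.32), Hpgd (12.48 ± 0.108 to 11.28 ± 0.111, −1.20), the p53-regulating ligase gene Mdm2 (−0.98), the stem cell antigen gene Cd34 (10.48 ± 0.0616 to 9.531 ± 0.105, −0.95), the osteopontin gene Spp1 (−0.86), the cell cycle inhibitor gene Cdkn2c (−0.85), the transcription factor gene Mef2c (−0.83) and Muc13 (−0.77). After the calprotectin genes the largest rises were those of Ngp (0.98), Stfa1 (0.96), Tgfbi (9.234 ± 0.0436 to 10.18 ± 0.0113, 0.95), the thrombospondin gene Thbs1 (0.89), the fibronectin gene Fn1 (0.86) and the lysozyme gene Lyz2 (0.81).

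Of 19 measured members of the Hoxa and Meis1 program 18 fell and 0 rose, also when adjusted over the list alone. Sox4 fell by 0.77. Camera called the list (adjusted p = 9.14e-25, but adjusted p = 0.0612 with an estimated correlation). Of 20 stem and progenitor genes 11 fell and 2 rose, against 12 and 2 adjusted over the list alone, Erg by 0.65 and Myb by 0.30 among them (camera adjusted p = 2.28e-05, and adjusted p = 0.434 with an estimated correlation). In the secondary granule and neutrophil list 24 of 30 rose and 0 fell, against 25 adjusted over the list alone, among them the leukotriene receptor gene Ltb4r1 (0.55) and the lactoferrin gene Ltf (0.54). Camera gave adjusted p = 9.59e-16, and adjusted p = 0.185 with an estimated correlation. Of 29 monocyte and macrophage genes 17 rose and 2 fell, against 19 and 2 adjusted over the list alone, including Fcgr3 (0.48) and Ly6c2 (0.40) (camera adjusted p = 1.97e-08, and adjusted p = 0.0612 with an estimated correlation). Of 11 primary granule genes 5 rose and 0 fell, also adjusted over the list alone, including Elane (0.32) and Prtn3 (0.24) (camera adjusted p = 0.0248, and adjusted p = 0.446 with an estimated correlation).

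Of 26 genes of the ATF4 response 10 rose and 0 fell, also adjusted over the list alone, with Cth at 0.27, Asns at 0.26 and the amino acid transporter gene Slc7a5 at 0.20 (camera adjusted p = 3.41e-05, and adjusted p = 0.434 with an estimated correlation). Of 24 cholesterol synthesis genes 9 rose and 1 fell, against 13 and 1 adjusted over the list alone. Sc5d (0.30), Mvd (0.27) and Fdps (0.18) rose (camera adjusted p = 0.000812, and adjusted p = 0.446 with an estimated correlation). Neither the type I interferon list (1 higher and 3 lower of 40, and 1 and 2 adjusted over the list alone) nor the Stat targets (10 higher and 5 lower of 25, also adjusted over the list alone) were called by camera, with adjusted p of 0.197 and 0.097. The number of calls was 1307 without DOX 2 and 1311 without DOX 3.

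With MLL-AF9 exposed to DOX, Hoxa9 and Meis1 fell, genes of secondary granules such as Ltf and Ngp rose, and inflammatory and immediate early genes rose. Hoxa9 went from 60.12 ± 2.81 to 19.67 ± 3.2 FPKM (−1.57 on the log2(FPKM + 1) scale, adjusted p = 0.000438 by limma) and Meis1 from 6.021 ± 0.549 to 1.16 ± 0.544 (−1.73, adjusted p = 0.00426). Ltf rose from 12.59 ± 2.35 to 147.8 ± 5.45 FPKM (3.47, adjusted p = 2.46e-05) and Ngp from 194.1 ± 19.2 to 1532 ± 112 (2.98, adjusted p = 2.46e-05). Hoxa10 went from 25.81 ± 5.04 to 15.85 ± 3.94 FPKM (−0.68), which missed the threshold (adjusted p = 0.0655) and passed it without DOX 3 (adjusted p = 0.0318) and with the replicate block (adjusted p = 0.0227). Of 10881 genes tested 1281 were called, 787 higher and 494 lower with DOX, and 283 changed by at least 1 log2 unit, 213 up and 70 down.

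Kmt2a went from 13.69 ± 0.255 to 5.605 ± 0.413 FPKM (−1.16, adjusted p = 0.00126). Mllt3, the other partner of this fusion, was at 3.946 ± 0.428 and 3.003 ± 0.991 FPKM (−0.33, adjusted p = 0.378) and was not called, and neither were Mllt10 (0), Picalm (0.27) and Dot1l (−0.21). Jak2 rose from 13.6 ± 1.37 to 25.87 ± 2.34 FPKM (0.88, adjusted p = 0.00385), whereas Jak1 (0.24), Jak3 (0.16), Tyk2 (0.26), Stat2, Stat3, Stat4, Stat5a, Stat5b and Stat6 were not called in this fit. The nearest was Stat6 (0.27, adjusted p = 0.0556, and 0.0497 with the stricter filter).

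Other large rises were those of Stfa2 (18.62 ± 5.61 to 159.6 ± 29.6 FPKM, 3.06) and the transcription factor gene Egr2 (1.987 ± 0.333 to 22.18 ± 1.59, 2.96). The small RNA entries Snord49a, Mir1892 and Mir8091 were at the table's lowest value of 0.01 in all DMSO libraries and at 3459 ± 1910, 368 ± 227 and 109 ± 53.8 FPKM with DOX, so no fold is given. Mir546 went the other way, from 150 ± 107 to 0.07741 ± 0.117 FPKM. The proton pump subunit gene Atp6v0c (8.395 ± 14.4 to 110.3 ± 7.54) and its pseudogene Atp6v0c-ps2 (69.51 ± 18.1 to 0.05883 ± 0.0603) moved in opposite directions. These are near-identical copies between which reads could be assigned either way, and the call of Atp6v0c was lost without each of the DMSO 2, DMSO 3, DOX 1, DOX 2 and DOX 3 libraries (adjusted p from 0.0643 to 0.0948). The largest falls besides were those of Hpgd (means of 209.7 and 14.79 FPKM, −3.74), C2cd4a (−3.17), Tctex1d1 (−2.68), the chemerin receptor gene Cmklr1 (12.45 ± 3.24 to 1.228 ± 0.179, −2.57), and the noncoding RNA genes Mira (−1.94) and Lincppara (−1.83).

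**Figure D1:**
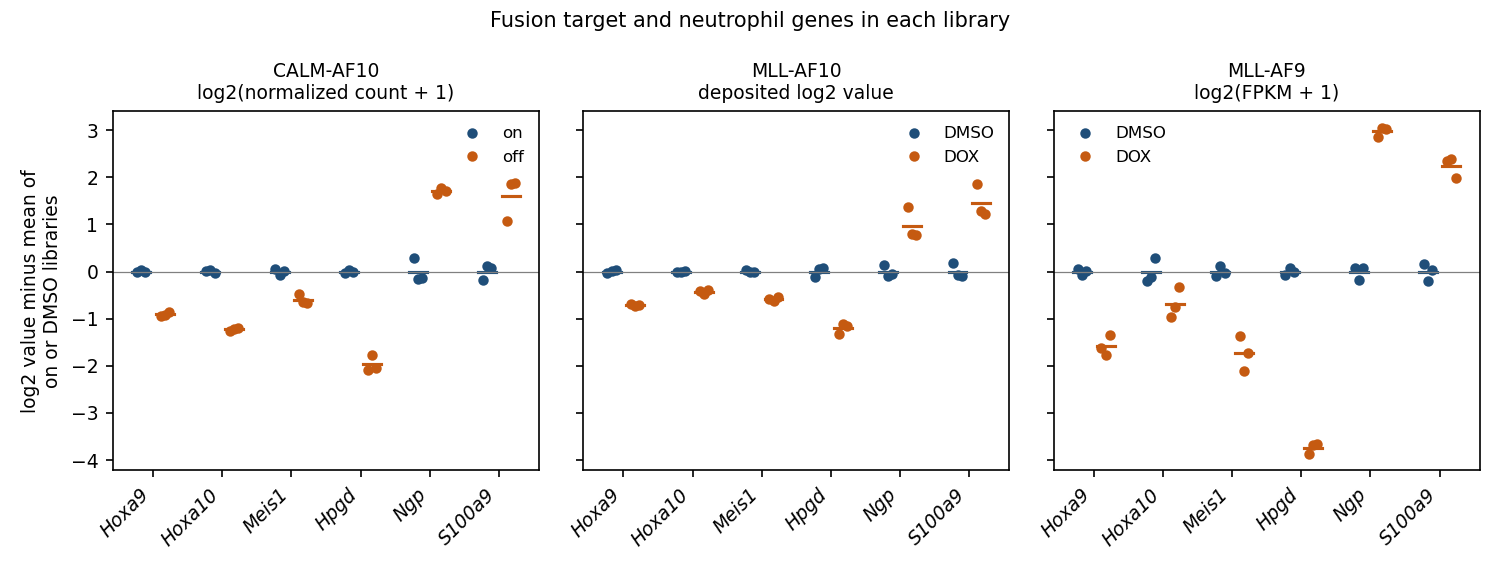
Log2 value of Hoxa9, Hoxa10, Meis1, Hpgd, Ngp and S100a9 in each library, minus the mean of the 3 libraries with the fusion on (CALM-AF10) or with DMSO (MLL-AF10 and MLL-AF9). Points are libraries and bars are group means. Hoxa9, Meis1 and Hpgd lay below and Ngp and S100a9 above every reference library in each of the 3 models. The log2 fold changes between groups in MLL-AF9 were −3.74 for Hpgd and 2.98 for Ngp.

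Of 19 measured members of the Hoxa and Meis1 program 13 fell and 0 rose in MLL-AF9, against 16 and 0 adjusted over the list alone. Hoxa7 fell by 1.48, the cyclin-dependent kinase gene Cdk6 from 172.8 ± 18.7 to 61.76 ± 6.04 FPKM (−1.47) and Myb from 186.5 ± 5.51 to 94.1 ± 1.01 (−0.98). Camera called the list (adjusted p = 1.2e-12, and 0.0143 with an estimated correlation). Of 15 stem and progenitor genes 4 fell and 0 rose, also adjusted over the list alone, Lmo2 by 0.70 among them (camera adjusted p = 0.01, and adjusted p = 0.0932 with an estimated correlation). In the secondary granule and neutrophil list 27 of 34 rose and 0 fell, against 31 adjusted over the list alone, including Retnlg (2.75) and Cd177 (1.73) (camera adjusted p = 3.16e-26, and 0.0258 with an estimated correlation). Of 32 monocyte and macrophage genes 16 rose and 0 fell, against 21 adjusted over the list alone. The scavenger receptor gene Msr1 (1.96), the cathepsin gene Ctsd (1147 ± 89.4 to 2713 ± 80 FPKM, 1.24) and Csf1r (0.66) rose (camera adjusted p = 5.28e-12, and adjusted p = 0.112 with an estimated correlation). Primary granule genes went both ways: of 11, 3 fell and 1 rose, against 4 and 1 adjusted over the list alone. Mpo (−0.91) and the cathepsin G gene Ctsg (−0.73) fell and Prss57 rose by 1.33 (camera adjusted p = 0.0166 for lower, and adjusted p = 0.274 with an estimated correlation).

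Of 33 NF-kB and inflammatory genes 21 rose and 0 fell with DOX in MLL-AF9, against 23 adjusted over the list alone. The chemokine genes Cxcl2 (106.2 ± 18.6 to 398 ± 32.7 FPKM, 1.91) and Ccl2 (1.52), the receptor antagonist gene Il1rn (1.13) and the inflammasome gene Nlrp3 (1.01) were among them (camera adjusted p = 2.52e-14, and 0.0258 with an estimated correlation). Of 19 immediate early and stress genes 14 rose and 0 fell, against 15 adjusted over the list alone, including Fosb (2.75), Fos (1.70) and Egr1 (1.67) (camera adjusted p = 2.57e-14, and 0.0143 with an estimated correlation). Of 23 Stat targets 13 rose and 0 fell, against 14 adjusted over the list alone, among them Socs3 (18.45 ± 1.44 to 54.18 ± 7.2 FPKM, 1.5), Cish (0.93) and Junb (0.89) (camera adjusted p = 5.81e-07, and adjusted p = 0.0913 with an estimated correlation). Of 31 Jak-Stat components 6 rose and 1 fell, against 8 and 1 adjusted over the list alone (camera adjusted p = 0.00126, and adjusted p = 0.0591 with an estimated correlation). Of 38 MYC and ribosome biogenesis genes 20 fell and 0 rose, against 27 adjusted over the list alone, with Nop2 at −0.62 and Mybbp1a at −0.57 (camera adjusted p = 1.33e-14, and 0.0316 with an estimated correlation).

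Of 44 cell cycle genes 10 fell and 0 rose in MLL-AF9, against 11 and 2 adjusted over the list alone, the replication gene Mcm5 by 0.45 and the nucleotide reductase gene Rrm2 by 0.35 (camera adjusted p = 1.39e-05, and adjusted p = 0.0932 with an estimated correlation). The call of Rrm2 was lost without DMSO 2 (adjusted p = 0.0611), without DMSO 3 (0.0602), with the block (0.0577) and with robust limma (0.0514). Of 24 p53 targets 8 rose and 1 fell, also adjusted over the list alone, with Btg2 at 1.59 and Plk2 at 1.17 (camera adjusted p = 0.0134, and adjusted p = 0.0932 with an estimated correlation). In the ATF4 list 5 of 26 fell and 2 rose, against 10 and 4 adjusted over the list alone. Cth (−0.83) and Psat1 (−0.49) fell and Ddit4 rose by 0.94 (camera adjusted p = 0.03 for lower, and adjusted p = 0.503 with an estimated correlation). The type I interferon list was not called, with 4 higher and 1 lower of 43, also adjusted over the list alone (camera adjusted p = 0.891). The number of calls was 764, 648 and 683 without DMSO 1, DMSO 2 and DMSO 3.

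In CALM-AF10 cells labelled Jak1 null, Jak1 itself was at 2070, 1916 and 1937 normalized counts, against 2444, 2438 and 2472 in the floxed libraries (log2 fold change −0.32, adjusted p = 2e-08 by edgeR). The deleted exons are not given in the sources used here, so reads from the rest of the gene check the deletion only in part. Interferon response, inflammatory, cholesterol synthesis and ATF4 response genes fell, and primary granule genes such as Mpo rose. Thbs1 went from 12370 ± 404 to 1228 ± 53.1 normalized counts (−3.34, adjusted p = 1.99e-33) and Mpo from 2250 ± 182 to 9005 ± 473 (2, adjusted p = 4.38e-26). Of 11607 genes tested 6467 were called, 3185 higher and 3282 lower in null cells, and 847 changed at least 2-fold, 194 up and 653 down.

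The largest falls were those of the transglutaminase gene Tgm2 (3157 ± 181 to 16.18 ± 6.67 normalized counts, −7.60), Bpifc (331.4 ± 19.8 to 4.284 ± 1.45, −6.23), the growth factor gene Tgfb2 (1003 ± 29.1 to 26.07 ± 4.68, −5.26), the stearoyl-CoA desaturase gene Scd1 (2131 ± 75.7 to 101.6 ± 36.9, −4.39), Olfml2b (−3.81), Rgs11 (−3.78), the cytokine gene Il33 (327.8 ± 11 to 30.89 ± 9.25, −3.40) and Thbs1. The largest rises were those of the surrogate light chain gene Igll1 (139 ± 10.8 to 1014 ± 21.4, 2.86), the receptor kinase gene Flt3 (101.5 ± 19.8 to 675.5 ± 31.1, 2.72), the endothelin receptor gene Ednra (2.36), the integrin gene Itgad (238.6 ± 11.2 to 1139 ± 30, 2.25), Scin (2.17), Asprv1 (2.17), Far2 (2.15) and Lypd6 (2.14).

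Hoxa9 (−0.05), Hoxa10 (−0.05) and Meis1 (0.08) were not called in the Jak1 comparison, with adjusted p of 0.256, 0.188 and 0.206, and neither were Kmt2a (0), Mllt3 (0.10) and Dot1l (−0.05). Picalm fell by 0.51 (7290 ± 104 to 5119 ± 138, adjusted p = 5.32e-15), and Mllt10 fell by 0.10 (adjusted p = 0.0135), a call lost without null 2 (adjusted p = 0.0768). The 863 tested genes of chromosome 2, where Mllt10 lies, had a median of −0.088 in this comparison, close to the change of Mllt10. Among the named Jak and Stat genes other than Jak1 itself, Stat4 fell most (481.8 ± 45.5 to 205.3 ± 8, −1.23), followed by Stat6 (−0.27), Jak2 (−0.22), Stat2 (−0.21), Jak3 (−0.17), Stat5b (−0.14) and Stat3 (−0.11). Tyk2 (−0.01) and Stat5a (0.06) were not called. The call of Jak3 was lost without floxed 2, null 1 or null 2 (adjusted p up to 0.171).

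Of 36 measured type I interferon response genes 24 fell and 4 rose, also adjusted over the list alone. The antiviral membrane protein genes Ifitm1 (7104 ± 289 to 2991 ± 194) and Ifitm3 (−1.08), Samd9l (−1.41) and the nucleic acid sensor gene Zbp1 (260.1 ± 27.7 to 42.56 ± 3.75, −2.62) fell (camera adjusted p = 1.47e-07, and 0.0324 with an estimated correlation). Of 25 Stat targets 20 fell and 3 rose, also adjusted over the list alone, including Il2ra (1167 ± 49.2 to 461.1 ± 15.2, −1.34), the cyclin gene Ccnd3 (−0.76), the survival gene Bcl2l1 (−0.70) and the feedback inhibitor gene Cish (−0.54). Camera gave adjusted p = 3.58e-05 for that list, and adjusted p = 0.238 with an estimated correlation. Of 28 NF-kB and inflammatory genes 19 fell and 5 rose, also adjusted over the list alone, with Ccl4 (574.4 ± 58.9 to 85.67 ± 12.5, −2.75), Nlrp3 (−2.63), Ccl3 (−1.77) and Cd14 (−1.46) among the fallen (camera adjusted p = 5.19e-07, and 0.0324 with an estimated correlation). Of 26 ATF4 response genes 23 fell and 0 rose, also adjusted over the list alone, including Trib3 (296.2 ± 5.52 to 72.95 ± 2.7, −2.02), Ddit4 (−1.57) and Atf4 itself (−0.40) (camera adjusted p = 3.76e-07, and 0.0324 with an estimated correlation). Of 23 cholesterol synthesis genes 21 fell and 0 rose, also adjusted over the list alone, including Lss (1836 ± 68.7 to 852.1 ± 5.8, −1.11), Mvd (−1), Fdps (−0.78) and Cyp51 (−0.69). Camera gave adjusted p = 5.53e-13 for that list, and adjusted p = 0.0807 with an estimated correlation.

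Of 11 primary granule genes 10 rose and 0 fell in Jak1 null cells, also adjusted over the list alone, including Mpo and Ctsg (0.51) (camera adjusted p = 1.51e-10, and adjusted p = 0.0807 with an estimated correlation). The secondary granule and neutrophil list went both ways, with 13 of 34 higher and 18 lower, also adjusted over the list alone. Mmp8 (1.68) and Ltf (1.43) rose and Cd177 (−0.83) fell. Its median was −0.235, its mean 0.021, and camera did not call it (adjusted p = 0.185). Of 28 monocyte and macrophage genes 15 rose and 8 fell, against 16 and 8 adjusted over the list alone, including Csf1r (95.96 ± 1.15 to 354 ± 6.14, 1.88) and Irf8 (1.13), and camera did not call the list (adjusted p = 0.0521). Of 38 MYC and ribosome biogenesis genes 26 rose and 1 fell, also adjusted over the list alone, with Wdr12 at 0.41, Dkc1 at 0.31 and Nop56 at 0.27 (camera adjusted p = 0.0111, and adjusted p = 0.238 with an estimated correlation). Of 44 cell cycle genes 23 rose and 8 fell, also adjusted over the list alone, including Mcm6 (0.55) and Mcm5 (0.42) (camera adjusted p = 0.0426, and adjusted p = 0.193 with an estimated correlation). Of 19 immediate early genes 12 fell and 3 rose, against 13 and 3 adjusted over the list alone, including Atf3 (−2.07) and Jund (−1.03) (camera adjusted p = 0.0284, and adjusted p = 0.238 with an estimated correlation). The Hoxa and Meis1 program had 5 members higher and 6 lower of 21, also adjusted over the list alone. Its median was −0.046 and its mean 0.028, with Flt3 and Bcl2 (0.77) higher and Pbx3 (−1.05) lower (camera adjusted p = 0.526). Of 32 Jak-Stat components 8 rose and 14 fell, also adjusted over the list alone. The receptor genes Csf3r (1.65) and Il6ra (1.26) rose and Il4ra (−1.05) fell, with no call by camera (adjusted p = 0.973).

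The labels give no sex, and all 4 measured Y-linked genes of the sex-linked list were lower in the null libraries. Ddx3y went from 565.2 ± 15.4 to 276.1 ± 18.1 normalized counts (−1.03), Eif2s3y from 478.6 ± 16.9 to 233.7 ± 8.7 (−1.04), Kdm5d from 284.3 ± 3.53 to 122.5 ± 4.32 (−1.22) and Uty from 177.3 ± 10.1 to 71.24 ± 16.5 (−1.33). The Jak1 groups thus differ in Y-linked RNA beside every gene group named above.

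**Figure D2:**
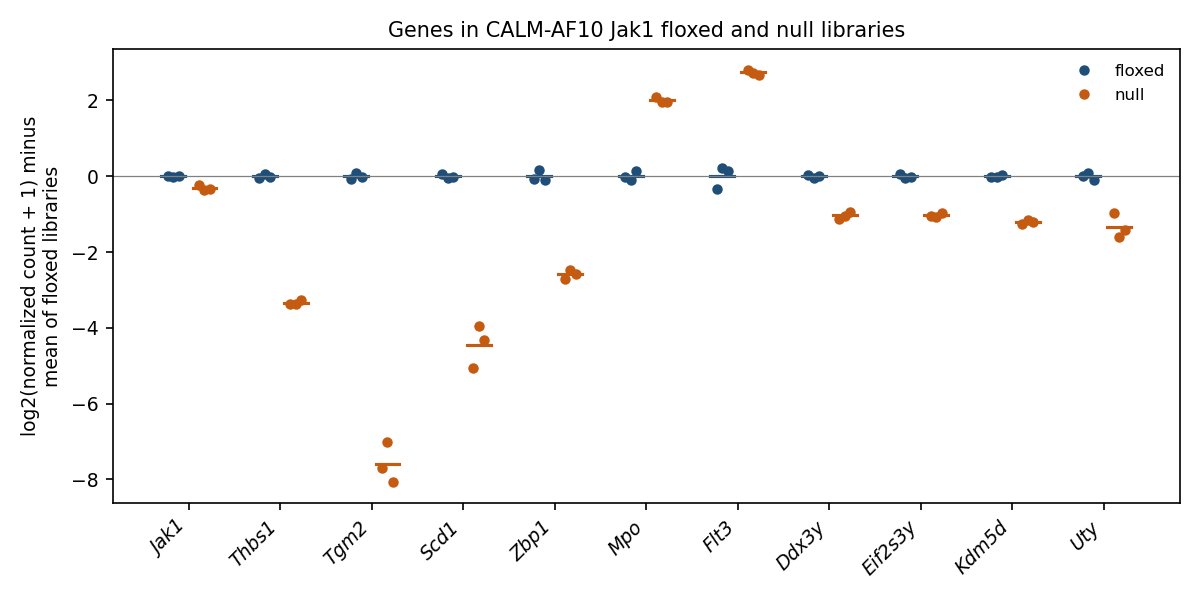
Log2(normalized count + 1) of 11 genes in each Jak1 floxed and null library, minus the mean of the 3 floxed libraries. Points are libraries and bars are group means. Jak1 was lower (log2 fold change −0.32), as was Tgm2 (−7.60), Mpo and Flt3 were higher, and all 4 Y-linked genes on the right were lower in each null library than in every floxed library.

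The responses of the 3 fusions overlapped. Genes higher in all 3 included Ngp, S100a8, S100a9, Stfa1 and Cd177, and genes lower in all 3 included Hoxa9, Hoxa7, Meis1, Mecom, Hpgd, Cd34, Erg and Cnksr3. Among the 9777 genes tested in all 3 models, 71 were higher in each against 1.9 for independent lists, and 30 were lower in each against 0.904. CALM-AF10 and MLL-AF10 shared 153 higher genes (25.9 for independent lists, Fisher's exact test adjusted p = 4.12e-88) and 147 lower genes (25.6, adjusted p = 1.54e-79). CALM-AF10 and MLL-AF9 shared 85 higher (18.5, adjusted p = 9.7e-35) and 39 lower genes (11.4, adjusted p = 2.14e-11), but 30 genes were lower with CALM-AF10 off and higher with DOX in MLL-AF9 (18.1, adjusted p = 0.00761). MLL-AF10 and MLL-AF9 shared 331 higher (78.3, adjusted p = 1.62e-140) and 147 lower genes (39.7, adjusted p = 1.72e-48). Across genes, which are not independent replicates, the log2 fold changes had Pearson's r of 0.451 and Spearman's rho of 0.429 for the pair with AF10, against 0.144 and 0.146 for CALM-AF10 with MLL-AF9 and 0.398 and 0.359 for MLL-AF10 with MLL-AF9. In both AF10 models the input was polyA RNA, Xist RNA was high and folds fell with gene length, unlike in MLL-AF9. An effect of the AF10 partner on these correlations cannot be told apart from those differences. With limma's robust fit in all models 16 and 12 genes were shared by all 3.

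The authors' deposited table lists 359 genes as lower with CALM-AF10 off, 966 with MLL-AF10 off and 887 with MLL-AF9 off. It gives 25 genes common to all 3 lists, among them Hpgd, Hoxa9, Hoxa10, Meis1 and Cd34, and 142 common to the AF10 fusions alone. The lists were chosen on these same libraries, so their direction is not independent evidence. Of the listed genes that were tested here, 357 of 357, 864 of 866 and 887 of 887 had lower values in the matching comparison, and 240, 626 and 427 were called lower. The off states in that table thus correspond to the DOX libraries of MLL-AF10 and MLL-AF9.

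Genes lower with CALM-AF10 off were also lower in Jak1 null cells more often than independent lists give. There were 177 such genes against 88.6 (Fisher's exact test adjusted p = 1.68e-25), including Ccl3, Ccl4, Ptgs2, Parp9, Samd9l, Il2ra and Pim2. The fusion partners were among them, Picalm (−0.78 with CALM-AF10 off and −0.51 in null cells) and Mllt10 (−0.48 and −0.1). Hoxa9, Hoxa10 and Meis1 were not called in null cells. Whether null cells held less of the fusion transcript itself was not tested, so its share in this overlap is unknown. Genes higher in both, with Elane, Mpo, Prtn3 and Ltf among them, were 68 against 70.9 (adjusted p = 1), but 84 against 69.2 without a filter and 4 against 0.217 for changes of at least 2-fold. In opposite directions, 119 genes were higher with CALM-AF10 off and lower in Jak1 null cells, against 70.6 (adjusted p = 1.06e-10). With limma's robust fit 58 genes were lower in both, against 28.5, and 14 higher in both, against 14.9. For MLL-AF9 the excess lay in the opposite directions. There 458 genes were higher with DOX and lower in Jak1 null cells against 209 (adjusted p = 5.99e-86), and 239 were lower with DOX and higher in null cells against 137 (adjusted p = 1.26e-23). For MLL-AF10, 497 genes were higher with DOX and lower in null cells against 294 (adjusted p = 3.68e-44), 377 were lower with DOX and higher in null cells against 267 (adjusted p = 8.02e-16), and 277 were lower in both against 253 (adjusted p = 0.0573). Of the 142 genes of the AF10-only list in the authors' deposited table, 125 were tested in the Jak1 experiment. Of these 69 were lower and 35 higher in null cells, where 55.7% of all tested genes were called in either direction. The lower ones made up 55.2%, against 28.3% of all genes (odds ratio 3.17, one-sided Fisher's exact test p = 2.05e-10). Of the 25 genes common to all 3 fusions 10 were lower (40%, one-sided Fisher's exact test p = 0.141) and 5 higher.

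**Figure D3:**
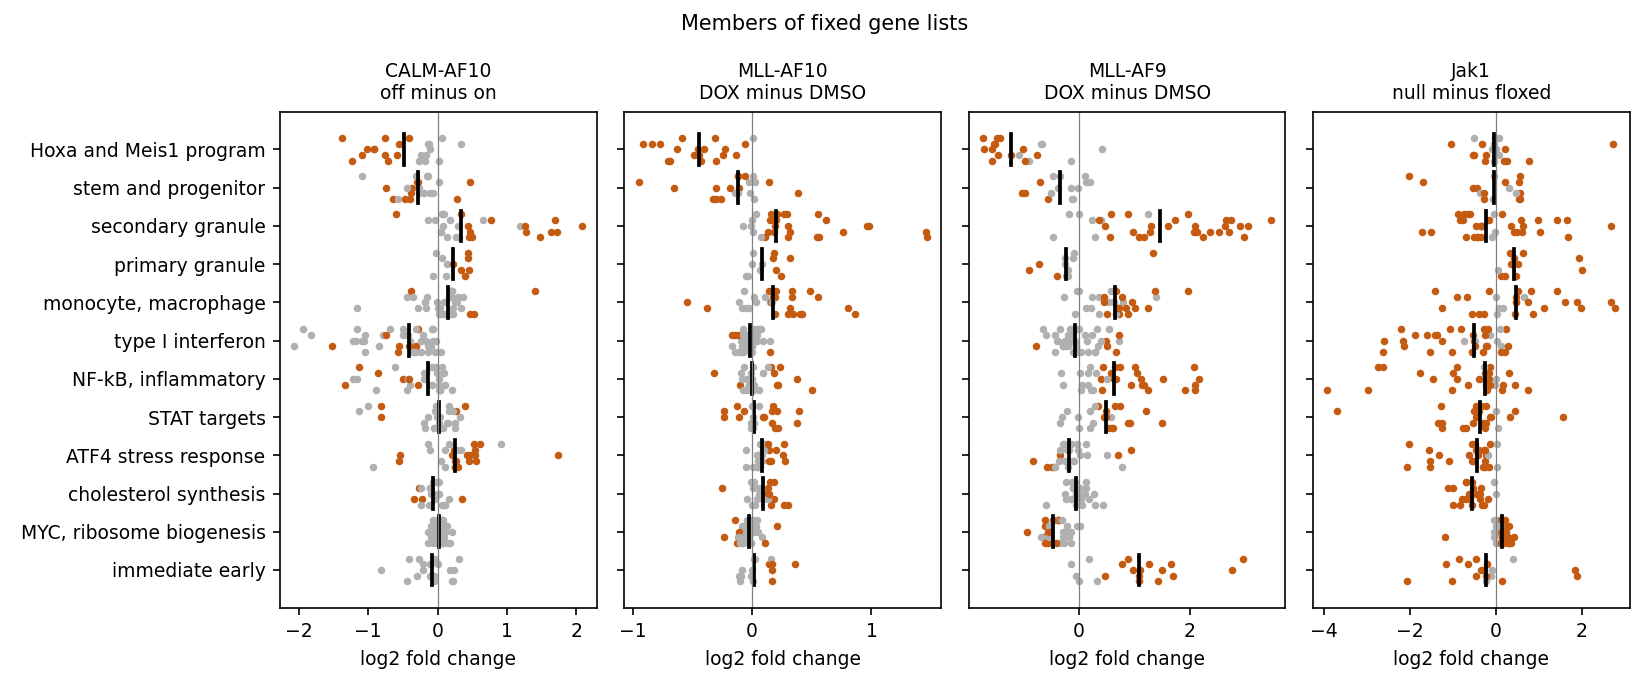
Log2 fold changes of the measured members of 12 fixed gene lists in the 4 comparisons. Each point is a gene, orange where called at adjusted p under 0.05 and grey where not, and black bars are list medians. Horizontal scales differ between panels. The Hoxa and Meis1 program had medians of −0.487, −0.443 and −1.219 in the fusion models and −0.046 in the Jak1 comparison, while cholesterol synthesis had −0.547 in the latter. Fold changes in MLL-AF10 are probably shrunken, so its medians cannot be compared in size with the others.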

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

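The responses of single genes to CALM-AF10 off and to DOX in MLL-AF9 were set against each other with the test planned for this. The 4 tests of the ATF4 list in the last paragraph were chosen only after its result was seen. Of 95 named genes 81 were tested in both models, and the responses of 65 differed past an adjusted p of 0.05. Many of them were named for large changes or small adjusted p in these same fits, which favours differences. The 65 are therefore no measure of how often genes at large differ. Each value below is the log2 fold change in MLL-AF9 minus that in CALM-AF10, with 3 libraries in each group. The models also differ in input RNA, in sex-linked RNA and in the unit of the tables, FPKM against counts. The values below are thus not differences between fusions alone.

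Many secondary granule, monocyte and inflammatory genes were raised more, or lowered less, in MLL-AF9, while the calprotectin genes S100a8 (0.48, adjusted p = 0.239) and S100a9 (0.6, adjusted p = 0.0558) were not told apart. Among granulocyte and monocyte genes the differences were 1.28 for Ngp, 1.37 for Ltf, 1.1 for Stfa1, 0.96 for Cd177, 2.25 for Msr1, 1.23 for Ctsd, 0.45 for Csf1r and 1.98 for Mmp12. Among inflammatory genes they were 3.13 for Cxcl2, 2.69 for Ccl2, 2.57 for Ptgs2, 1.63 for Il1rn, 1.57 for Ccl4, 1.43 for Ccl3 and 0.99 for Nlrp3. Among interferon response genes they were 1.24 for Ifit1 and 0.47 for Samd9l, while Parp9 was not told apart (0.35, adjusted p = 0.107), and 13 of 43 list members were more positive in MLL-AF9 and 0 more negative. For the immediate early genes Fosb, Egr2, Fos, Egr1 and Junb they were 3.56, 3.23, 2, 1.88 and 0.67. Over the whole lists 22 of 32 NF-kB and inflammatory genes, 14 of 19 immediate early genes, 16 of 32 monocyte genes and 18 of 29 secondary granule genes were more positive in MLL-AF9, and 0 were more negative in each.

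Signalling and stress genes with more positive responses in MLL-AF9 were Socs3 (1.11), Cish (0.68), Jak2 (0.64), Jak3 (0.46), Jak1 (0.3), Stat6 (0.26), Plk2 (1.88), Btg2 (1.5) and Ddit4 (1.07). The others were Ipcef1 (1.07), Lipg (0.78) and the fusion loci Picalm (1.06) and Mllt10 (0.48), which belong to CALM-AF10. The response of Hoxa10, which was not called in MLL-AF9, was less negative there, with a difference of 0.55. Those of Hoxa9 (−0.66), Hoxa7 (−0.73), Meis1 (−1.14), Cdk6 (−1.3), Myb (−0.88) and Lmo2 (−0.42) were more negative in MLL-AF9. Snord49a, at the lowest value of the table in the MLL-AF9 DMSO libraries, gave 11.38, a number that depends on the pseudocount.

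Also more negative in MLL-AF9 were Hpgd (−1.79), Cmklr1 (−2.68), Tctex1d1 (−1.47), C2cd4a (−1.37), Mira (−1.1), Lincppara (−1.51), Fam101b (−0.63) and the MLL locus Kmt2a (−1.2). The same direction was found for 8 of 11 primary granule genes, among them Mpo (−1.24), Ctsg (−0.87), Prtn3 (−0.62) and Elane (−0.55), with Prss57 (0.9) as the 1 more positive member. It was also found for the growth genes Nop2 (−0.61), Mybbp1a (−0.59), Mcm5 (−0.51) and Rrm2 (−0.32). ATF4 response genes differed in that direction too: Cth (−2.58), Asns (−0.87), Psat1 (−0.76), Pck2 (−0.69) and Mthfd2 (−0.67). Of 38 MYC and ribosome biogenesis genes 28 were more negative in MLL-AF9 and 0 more positive.

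The ATF4 list was higher in CALM-AF10 off (adjusted p = 0.105 with an estimated correlation) and MLL-AF10 with DOX (adjusted p = 0.434 with an estimated correlation, and 4 of 10 splits gave as small a p), and not in MLL-AF9 with DOX. For the list in MLL-AF9, too, 4 of 10 splits gave as small a p. No source used here says whether the off libraries were given DOX or DMSO. An effect of doxycycline alike in every model was therefore looked at both ways. With off as DOX, 18 of 26 members were more negative in MLL-AF9 than in CALM-AF10 and 3 more positive. With off as DMSO, all 9 members called in CALM-AF10 and in MLL-AF10 would have responded to DOX with opposite signs. Both counts restate the pattern for which the list was picked, so they do not test doxycycline apart from it. Without off 3, the shallowest library, the list's median in CALM-AF10 was 0.261, against 0.257 with all libraries, which argues against that library as the source. The median lay 0.26 above that of the genes outside the list. Camera's call already rests on such a difference, so this is no separate test of scaling. Open remain an effect of doxycycline, the different input RNA of MLL-AF9, and an effect of the AF10 fusions, which was not tested apart from treatment. The MLL-AF9 cells also differed from both AF10 models in sex-linked RNA, as given below, which was not tested apart either. Doxycycline doses or times may differ between models, and no source used here gives them.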

How the results depend on the processing

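Named genes that were called kept their direction in all settings that tested them. Counts of called genes depended most on single CALM-AF10 libraries and on the size of change asked for. The alternatives for shared calls, for the difference between fusions and for the Jak1 level, and the fit of MLL-AF10 without both libraries numbered 1, were chosen after seeing the data.

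With CALM-AF10 off 648 genes were called. Leaving out 1 library gave 146 (without on 2) to 944 (without off 3), with 343, 163, 484 and 253 without on 1, on 3, off 1 and off 2. Of the 648 genes 145 were among the 146. With the replicate block 1048 genes were called, 640 of them among the 648, and with limma without trend and robust 222, of which 202 were. DESeq2 gave 864. Asking for a 2-fold change left 76. In MLL-AF10 2089 genes were called, and 1307 (without DOX 2) to 2396 (without DMSO 1) with 1 library left out. The block gave 3102, the fit without both libraries numbered 1 2927, and asking for a change of 1 log2 unit left 5. In MLL-AF9 1281 genes were called, and 648 (without DMSO 2) to 1036 (without DOX 1) with 1 library left out. The block gave 781, of which 752 were among the 1281, and a change of at least 1 log2 unit left 283. In the Jak1 comparison 6467 genes were called. Leaving out 1 library gave 5819 to 6145, DESeq2 gave 5172, and asking for a 2-fold change left 847.

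Of 94 tests of gene lists 42 were past the threshold with the preset correlation, 10 with an estimated correlation, 43 with the block and 55 with fry. With the block and an estimated correlation together the smallest adjusted p was 0.12. The 10 were 2 lists in CALM-AF10, 5 in MLL-AF9 and 3 in the Jak1 comparison, and 0 in MLL-AF10. Genes called in the same direction in all 3 fusions were 71 higher and 30 lower ones, and 3 in sum when a change of at least 1 log2 unit was asked for, 28 with robust limma and 119 with the block. Only 5 MLL-AF10 genes passed that fold threshold on their probably shrunken scale, which caps the count of 3. Genes lower with CALM-AF10 off and in Jak1 null cells were 177, and 16 with the fold threshold (2.03 for independent lists), 274 with the block (145) and 58 with robust limma (28.5). The responses of 62 to 67 named genes differed between CALM-AF10 and MLL-AF9 over the alternatives, against 65. The log2 fold change of Jak1 in null cells ranged from −0.349 to −0.295, with adjusted p from 1.11e-14 to 0.00228.

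Of the named genes called, 28 of 42 in CALM-AF10, 40 of 44 in MLL-AF10, 49 of 51 in MLL-AF9 and 66 of 70 in the Jak1 comparison were called in every setting that tested them, and 0 changed direction. The stricter filter tested only 42 of the 44 in MLL-AF10 and 50 of the 51 in MLL-AF9. In CALM-AF10 the calls of 12 were lost without on 2, of 10 without on 3, of 4 without off 2 and of 2 each without on 1 and off 1. Robust limma lost 12, among them Il2ra (adjusted p = 0.076). Gained were Tyk2 without off 3 (adjusted p = 0.0265), with DESeq2 (0.024) and with RLE (0.0496), and Stat2 with the block (0.0346). In the Jak1 comparison robust limma lost 4, among them Mllt10 (adjusted p = 0.0624), Jak3 (0.0929) and Stat3 (0.054). DESeq2 lost 2 there, among them Jak3 (0.104).

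For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The number of splits with as many called genes as the real one, itself included, was 1 in each comparison. The real and highest other counts were 648 and 0 in CALM-AF10, 2089 and 0 in MLL-AF10, 1281 and 3 in MLL-AF9, and 6467 and 0 for Jak1. For called lists 5 splits gave as many in CALM-AF10 (10 in the real split, 15 at most in the others), 4 in MLL-AF10 (8 and 12), 1 in MLL-AF9 (14 and 11) and 3 for Jak1 (10 and 10). Of the 42 called lists 29 had their smallest p in the real split. In CALM-AF10 3 of the 10 splits gave as small a p for the type I interferon list, and 3 for the NF-kB list. In MLL-AF10 it was 4 for the cholesterol and ATF4 lists and 3 for the primary granule list, and in MLL-AF9 4 for the ATF4 list. For Jak1 it was 5 for the MYC list and 3 for the immediate early list. In MLL-AF10, where same-numbered libraries went together weakly, the splits that part every pair called 0 other genes and at most 7 lists.

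Groups did not overlap for 29.9%, 36.3%, 34% and 60.9% of the genes tested in CALM-AF10, MLL-AF10, MLL-AF9 and Jak1, against 10% by chance. Pseudocount and rescaling do not apply to the count tables, nor DESeq2 and RLE to the others, and a pseudocount of 5 was not run.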

Other observations

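The models differed in sex-linked RNA. Xist, the RNA that silences an X chromosome in female cells, was at 18200 to 59620 counts in the CALM-AF10 libraries and at 12.65 to 13.07 log2 units in MLL-AF10, where Ddx3y was at 0 to 1 counts and at 0. In MLL-AF9 Xist was at 0.01 to 0.15 FPKM and Ddx3y at 17.22 to 19.47. In the Jak1 table Xist was at 0 to 1 counts and Ddx3y at 254 to 600. By these genes the inducible CALM-AF10 and MLL-AF10 cells were female, and the cells of the MLL-AF9 and Jak1 experiments male. The tests of Y-linked genes and of the interferon list below were chosen only after those results were seen.

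The fall of Ddx3y, Eif2s3y, Kdm5d and Uty in the Jak1 null libraries needs an explanation other than sex. Cells with 2 X chromosomes in the null cultures are argued against by Xist, whose share of counts there was 0.00164% of that in the CALM-AF10 table. A scaling factor would move every gene alike, whereas the median of the Y-linked genes lay at −1.134 relative to all other genes. That value restates their fall and is no separate test. Loss of the Y chromosome in part of the null cells is a candidate explanation: all 4 genes fell, and their folds were not told apart by a test of homogeneity (Cochran's Q of the edgeR estimates against a chi-square distribution, p = 0.0819), which is approximate with 3 libraries in each group and does not show them equal. The Jak1 comparison also had 39.7% of 863 chromosome 2 genes lower and 21% higher (median −0.088), while the medians of the other autosomes lay between −0.015 and 0.049. Of 343 X chromosome genes 31.5% were higher and 19.5% lower, with a median of 0.057, above that of every autosome. If the null cells descend from a few cells, other differences between the groups may come from that descent and not from Jak1, and this stays open because no deleted clone is labelled apart.

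The type I interferon list was lower with CALM-AF10 off (camera adjusted p = 4.69e-10, but adjusted p = 0.522 with an estimated correlation). The median deviation of its 43 genes from their means over all libraries was −0.12, 0.40 and 0.42 in the on libraries and −0.41, −0.06 and −0.06 in the off libraries. A single library as the whole source is argued against by the median, which was −0.277 at its closest to 0 (without off 1) and −0.411 with all libraries, although the number of fallen members was 7 with all and 20, 0, 1, 1, 3 and 8 without on 1, on 2, on 3, off 1, off 2 and off 3. The median lay at −0.408 relative to the genes outside the list, but camera's call already rests on such a difference, so this is no separate test of scaling. An interferon level that differs between cultures whatever the state of the fusion cannot be told apart from an effect of the fusion, since 3 of the 10 splits gave a difference between the group means of these medians as large (0.411 in the real split, 0.452 at most in the others). These splits take no account of replicate numbers, and each off library lay below the on library of its number. With the replicate block 28 members fell and 0 rose, with a median of −0.384. Camera with the block gave adjusted p = 2.53e-31, but adjusted p = 0.186 with an estimated correlation as well.

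Oxidative phosphorylation genes were past the threshold of camera in both AF10 models, where folds also fell with gene length (Spearman's rho −0.19 in CALM-AF10 and −0.092 in MLL-AF10, against 0.018 in MLL-AF9 and −0.028 in Jak1), a trend that was not taken out. In CALM-AF10 1 of 35 rose and 0 fell, also adjusted over the list alone (adjusted p = 6.2e-05, but adjusted p = 0.417 with an estimated correlation). In MLL-AF10 5 rose and 0 fell, against 4 adjusted over the list alone (adjusted p = 0.00652, and adjusted p = 0.434 with an estimated correlation). The list was not called in MLL-AF9 (adjusted p = 0.0781, 0 higher and 0 lower) or in the Jak1 comparison (0.0799, 16 higher and 3 lower). The fusion and target loci were called lower as a list in CALM-AF10 (2 of 6 fell, also adjusted over the list alone, adjusted p = 0.000169, and adjusted p = 0.098 with an estimated correlation) and not in MLL-AF10 (0.257), MLL-AF9 (0.607) or Jak1 (0.204).

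Markers of other cell types were tested as lists. T and NK genes were lower in CALM-AF10 (1 of 6 fell, also adjusted over the list alone, camera adjusted p = 0.026, and adjusted p = 0.219 with an estimated correlation), and were not called in Jak1 (0.711, 2 higher and 3 lower of 6). Megakaryocyte genes were higher in MLL-AF9 (1 of 5 rose, 3 adjusted over the list alone, adjusted p = 0.0389, and adjusted p = 0.21 with an estimated correlation) and were not called in CALM-AF10 (0.0776), MLL-AF10 (0.0842) or Jak1 (0.773, 1 higher and 3 lower of 5, and 1 and 4 adjusted over the list alone). B lymphoid genes were higher in Jak1 null cells (2 of 5 rose and 1 fell, also adjusted over the list alone, adjusted p = 0.000785, and adjusted p = 0.238 with an estimated correlation), with Igll1 and Vpreb1 (16.32 ± 6.07 to 98.19 ± 14.5 normalized counts) as the risen ones, and were not called in CALM-AF10 (0.414). Mast cell and basophil genes were not called in CALM-AF10 (0.887), MLL-AF10 (0.68), MLL-AF9 (0.454) or Jak1 (0.812, 2 higher and 2 lower of 8, median 0.131 and mean −0.122). Dendritic genes were not called in CALM-AF10 (0.205) or Jak1 (0.0978, 2 higher and 1 lower of 5), stromal and endothelial genes not in CALM-AF10 (0.379) or Jak1 (0.154, 3 higher and 3 lower of 7), and erythroid genes not in CALM-AF10 (0.556). Eosinophil genes in CALM-AF10 were not called (0 of 6 rose and 1 fell, 4 and 1 adjusted over the list alone, adjusted p = 0.0832). They were with the block (0.0056), but not with the block and an estimated correlation (adjusted p = 0.262). Of lists with under 5 measured members, those in MLL-AF10 had 3 of 4 dendritic, 2 of 3 T and NK, 2 of 3 stromal and 1 of 3 erythroid genes lower, and 0 of 4 eosinophil and 0 of 4 B lymphoid genes called. Those in MLL-AF9 had 2 of 3 dendritic and 1 of 2 B lymphoid genes higher, 2 of 2 erythroid, 1 of 3 T and NK and 1 of 3 stromal genes lower, and 0 of 2 eosinophil genes called. In Jak1 2 of 3 eosinophil genes were lower, and 1 of 4 erythroid genes was higher and 1 lower. These numbers were also found adjusted over the list alone, except that 2 stromal genes then rose in MLL-AF9. No gene of the mitochondrial genome was measured in these tables.

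Of the other lists that camera did not call, interferon gamma genes gave 2 lower of 36 in CALM-AF10 (4 adjusted over the list alone, adjusted p = 0.165) and 1 higher and 6 lower of 28 in MLL-AF10 (2 and 6, adjusted p = 0.0842). They gave 5 higher and 3 lower of 32 in MLL-AF9 (6 and 4, adjusted p = 0.463), and 13 higher and 8 lower of 32 in Jak1 (also adjusted over the list alone, adjusted p = 0.0647, median 0.068 and mean −0.054). Housekeeping genes gave 0 calls of 12 in CALM-AF10 (0.732) and MLL-AF9 (0.395), 1 higher and 1 lower in MLL-AF10 (0.487), and 4 higher and 5 lower in Jak1 (0.0986), with the same numbers adjusted over the list alone. In CALM-AF10 the lists of monocyte (0.0965), cell cycle (0.0651), MYC (0.338), p53 (0.179), cholesterol (0.0651), immediate early (0.474) and Jak-Stat genes (0.753) were not called. In MLL-AF10 this held for Jak-Stat (0.154), NF-kB (0.257), cell cycle (0.137), MYC (0.0842), p53 (0.109) and immediate early genes (0.197), in MLL-AF9 for cholesterol genes (0.783), and in Jak1 for stem and progenitor (0.59) and p53 genes (0.45).

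Of the 71 genes higher in all 3 fusions with the fusion off or DOX, 35 were lower and 21 higher in Jak1 null cells, and of the 30 lower in all 3, 29 were tested there, with 12 lower and 5 higher. Cdkn2c, lower in each fusion, fell by 1.72 in Jak1 null cells, Hpgd by 0.68 and Ngp by 0.69.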
